A study of Homo sapiens with 45 samples.

How the data were processed

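The series profiled RNA of 15 breast cancer cell lines, each with 3 replicates, and all 45 libraries were used. Per the labels' protocols, total RNA was isolated with RNeasy kits, ribosomal RNA was depleted with Ribo-Zero Gold, and libraries were made from 1000 ng of RNA with ScriptSeq v2. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0.422, checked with FastQC and MultiQC, trimmed with Trimmomatic, aligned to GRCh38.p12 with STAR and assigned to genes with featureCounts. The versions of the tools after bcl2fastq, the gene annotation release, the strand setting and the handling of reads that align to several places are not given in the sources used here. The authors deposited a table of raw counts per gene and library, and no column of that table was left out.

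The table held 64485 genes, of which 55100 had at least 1 count. Gene identifiers were matched to GENCODE 29 (GRCh38) without their version suffix, and 58275 (90.4%) matched. Another 45 identifiers belonged to the copies of pseudoautosomal genes on Y. The 6165 without a match held 0.0785% of all counts and were kept in the tests without a type or position. Symbols, gene types and positions come from this release. The libraries held 2312138 to 14653677 counts (median 6263573), and the report gives the total of each. Precision is given as the SD or SE between replicates or lines, and for genes with few reads as Poisson intervals. The SE of an edgeR estimate is its absolute size divided by the square root of the F statistic of its test.

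From the deposited counts, CPM and log2 CPM were computed with TMM scaling in edgeR 4.0.16 (R 4.3.3, prior count 2). The CPM of a line is given as a mean with its SD over 3 replicates where not stated otherwise. Fold bounds, Poisson ratios, values of the histone cluster and the thresholds for silent genes and run sets used summed libraries without TMM scaling. These have no SD. Genes were kept by filterByExpr with the design of the fit, a minimum count of 10 and a minimum total of 15. Benjamini-Hochberg correction was used throughout at 0.05, and tests are two-sided. Differences among lines used the edgeR quasi-likelihood F test on 45 libraries, and each line was compared with the mean of the other 14 lines in the same fit, with an absolute log2 fold change of at least 1. Where a line had 0 counts of a gene, the fold against the median of the other lines is a bound from a floor of 3 counts over the summed libraries of the line. Where it had 1 to 6 counts, the ratio has an exact 95% Poisson interval.

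Relations across lines took the line as the unit, with counts summed over its 3 replicates. The slope of each gene on log2 CPM of MYC was tested by edgeR over 15 line sums, and 5 L-15 lines were compared with 8 RPMI 1640 lines in the same way, with an absolute log2 fold change of at least 1. BT-20 and Hs578T, alone in their media, were left out of the comparison by medium. A list score is the mean of the members' log2 CPM, each scaled to mean 0 and SD 1 over the lines. MYC was left out of every list set against MYC or complex I. It stayed in the MYC network list for the comparison by medium and for single lines. Pearson and Spearman correlations of scores used 100000 permutations of the lines, for which the smallest possible p is 0.00001, and were recomputed without the 2 lines farthest from the median of the x axis. Score differences by medium used an exact permutation test over 1287 splits, for which the smallest possible p is 0.00078. The camera test of limma 3.58.1 used an estimated correlation between genes. No line was assigned to a class by its MYC level.

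In the first form of the MYC slope fit the filter had an intercept-only design, which kept 13151 genes and gave 2 rising and 34 falling genes. The form with the design of the fit, which keeps 26614 genes, was made the main one after those counts had been seen. TMM factors are computed from the kept genes, so list scores also depend on this choice, and both values are given for each list set against MYC or complex I whose sign or call differs.

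Before the data were examined, 34 gene lists, the tests, most alternatives and the rule for named genes were fixed. The lists cover complex I nuclear subunits and assembly factors, mitochondrial genome mRNAs, complexes III, IV and V, TCA cycle enzymes, glutamine uptake and use, glycolysis and lactate, and pyruvate entry to mitochondria. They also cover serine and one-carbon metabolism, fatty acid oxidation, mitochondrial biogenesis regulators, mitochondrial and cytosolic ribosomes, ribosome biogenesis and nucleolus, other textbook MYC targets, the MYC network, and the 8q24 neighbours of MYC. The remaining lists are cell cycle, integrated stress response, hypoxia, NRF2 and glutathione, cholesterol synthesis, interferon, short and nuclear RNAs, histones, and markers of epithelial, mesenchymal, basal, luminal, blood, endothelial and fibroblast cells. The named genes are, for each line, the 3 protein-coding genes with the largest positive and the 1 with the largest negative log2 fold change among those that passed, with a mean of at least 10 CPM and all replicates on the same side. For the MYC slope and for medium they are the 10 with the smallest p on each side, with a mean of at least 5 CPM, whether or not they passed. Up to 4 members of each list with the smallest p and a short set of MYC, glutamine, lactate, receptor and lineage genes were added, and the values of some of these are not given. The gene silenced X chromosomes express and Y-linked genes were left out.

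Correlations between replicates were checked. Correlations of log2 CPM were 0.926 to 0.991 within lines and 0.736 to 0.905 between lines, and each of the 45 libraries was closest to its own line. The lowest value within lines was that of Hs578T, and the lowest of any other line was 0.972. The variance between replicates was 2.5 to 28.2 times the Poisson variance for genes with at least 20 counts. Deviations of libraries from their line mean had a mean correlation of 0.059 between libraries of the same run in runs 3 to 5 and 0.048 in runs 1 and 2, and 33.3% of these pairs exceeded 0.1, so samples were not treated as paired and the run entered as a block in an alternative fit.

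Alternatives were DESeq2 1.42.0 size factors and tests, no filter beyond 1 count, no fold minimum, the run as a replicate block, limma-voom on libraries with the line as a random effect, comparison within the set of runs, and L-15 as a covariate. Others were only the lines of runs 3 to 5, only RPMI lines, MYC and genes from different replicates, medians of scaled members, and each replicate and each line left out in turn. The intercept-only filter was the first form of the MYC slope fit and became an alternative after its results had been seen. Its use for scaling and the removal of Hs578T replicate 2 were added after seeing the data. Figures were drawn with Python 3.11.15.

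The tests were tested on counts simulated from the real gene means, library sizes and dispersions, with effects put into 200 genes. Apart from these effects, each gene had 1 mean in all lines. For single lines and for runs the dispersions were those between replicates, so real differences between lines were not simulated. For the MYC slope and for medium the dispersions were those between line sums, so differences between lines entered as random spread. For 1 line against the others, 100% of changed genes were recovered at a log2 size of 2 and 51% at 1, with 1.3% false calls, and the F test recovered 86.5% with 7.5% false calls. The 51% also reflects the fold minimum of 1 log2 unit, since the median estimate at that size was 1. For the MYC slope 14% were recovered at a slope of 1 and 0% at 0.5 by edgeR, with 6.7% false calls. For medium 88% were recovered at a log2 size of 4 and 27% at 2, with 2.5% false calls. Between runs 100% were recovered at 1 and 89% at 0.5, with 1.6% false calls.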

Results

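RNA was profiled in 15 untreated human breast cancer cell lines, with 3 libraries per line and 45 libraries in all. Each library was made from total RNA depleted of ribosomal RNA, and each measurement was the number of reads assigned to a gene. By growth medium, 8 lines were kept in RPMI 1640 (HCC70, HCC38, HCC1937, HCC1806, HCC1395, HCC1187, HCC1143 and BT-549), 5 in L-15 (MDA-MB-468, MDA-MB-231, MDA-MB-453, MDA-MB-157 and MDA-MB-436), 1 in EMEM (BT-20) and 1 in DMEM (Hs578T). L-15 is a medium buffered for use in air that supplies galactose and pyruvate in place of glucose. HCC1143, HCC38, Hs578T and MDA-MB-231 were sequenced in runs 1 and 2, and the other 11 lines in runs 3, 4 and 5 with 1 library of each line in each run. The labels do not say whether the 3 replicates of a line came from separate cultures, so p-values between lines measure the spread between these samples, which may be technical.

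Total counts lay between 2312138 (Hs578T replicate 2) and 14653677 (HCC70 replicate 3), with a median of 6263573. In the order of replicates 1, 2 and 3, the libraries of BT-20 held 7081675, 6157076 and 6911370 counts, those of BT-549 5996676, 5931618 and 10180173, and those of HCC1143 5600637, 4587650 and 5710951. The libraries of HCC1187 held 6433465, 5306222 and 5524428 counts, those of HCC1395 6263573, 8578313 and 10206100, and those of HCC1806 7532358, 6896428 and 9486153. The libraries of HCC1937 held 6685074, 7202097 and 11342442 counts, those of HCC38 6657266, 9854548 and 6130357, and those of HCC70 8389590, 10388614 and 14653677. The libraries of Hs578T held 8438261, 2312138 and 5584902 counts, those of MDA-MB-157 5502463, 4308892 and 4880950, and those of MDA-MB-231 4949251, 6070035 and 4515567. The libraries of MDA-MB-436 held 5765185, 6342703 and 6565166 counts, those of MDA-MB-453 4930759, 5268086 and 6561309, and those of MDA-MB-468 5982750, 7182448 and 5978575. Between 27967 and 40272 genes had at least 1 count in a library (median 33873). Mitochondrial transcripts took 0.0502% to 0.782% of the counts. The highest number of genes detected and the highest mitochondrial share were both in Hs578T replicate 2, the library with the fewest counts.

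The first comparison asked how the transcriptomes of the 15 lines differ. Epithelial junction and keratin genes divided the lines. Of 23 measured epithelial genes, 20 to 22 were higher than the mean of the other lines in BT-20, HCC1143, HCC1187, HCC1806, HCC1937, HCC38, HCC70, MDA-MB-453 and MDA-MB-468. They were lower for 18 genes in BT-549, MDA-MB-157 and MDA-MB-436, for 19 in HCC1395 and for 20 in Hs578T. MDA-MB-231 had 4 higher and 10 lower. The adhesion gene CDH1 (E-cadherin) ranged from 683 ± 44.2 CPM (SD, n = 3) in HCC70 to 0.421 ± 0.183 CPM in HCC1395. The intermediate filament gene VIM ranged from 3590 ± 1570 CPM in Hs578T to 2.42 ± 0.275 CPM in HCC1937, and the repressor of epithelial genes ZEB1 from 186 ± 11 CPM in BT-549 to 1.23 ± 0.616 CPM in HCC1806. Of 22 mesenchymal genes, 21 were higher in Hs578T, 18 in BT-549 and 17 in MDA-MB-157, while 18 were lower in MDA-MB-468 and 15 in HCC70 and in MDA-MB-453. In a principal component analysis of the lines, component 1 (21.5% of the variance) ran from -128.1 (HCC70) to 104.6 (Hs578T), and component 2 (10.5%) was highest in MDA-MB-453 (135.2).

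Differentiation genes singled out a few lines. The luminal list, which holds hormone receptor and secretory genes, was higher for 14 of 18 genes in MDA-MB-453. ERBB2 there reached 515 ± 25.8 CPM (SD, n = 3) and the pioneer factor FOXA1 404 ± 85.3 CPM. The estrogen receptor ESR1 did not exceed 22.6 ± 2.14 CPM in any line (HCC1937). Of 21 basal keratinocyte genes, 18 were higher in HCC1806, 16 in HCC1143 and in HCC1937, and 15 in HCC70, while 17 were lower in HCC1395. The basal keratin KRT5 stood at 2450 ± 154 CPM in HCC1806, and the growth factor receptor EGFR at 1890 ± 698 CPM in MDA-MB-468 against 2.4 ± 1.05 CPM in MDA-MB-453. Of 9 fibroblast genes, 9 were higher in Hs578T and 7 in MDA-MB-157. Among 7 endothelial genes the score was highest in MDA-MB-231 (1.04 ± 0.11), and among 6 blood cell genes in Hs578T (0.67 ± 0.77).

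The genes with the largest differences in single lines came from many pathways. The matrix protein gene POSTN (ENSG00000133110.14, chromosome 13, 37562583 to 37598844) reached 7260 ± 4140 CPM (SD, n = 3) in Hs578T, with a mean of 3.65 CPM in the other lines. SPARC, another matrix gene, reached 3950 ± 371 CPM in MDA-MB-157, and ELN, which encodes elastin, 572 ± 66.5 CPM in HCC1187. CLCA2, a chloride channel regulator, reached 4110 ± 270 CPM in MDA-MB-453 against a mean of 8.59 CPM elsewhere. TCN1, a vitamin B12 carrier, reached 1280 ± 63.7 CPM and the protease inhibitor SERPINB3 878 ± 92.8 CPM in HCC70. The cytokine IL1B reached 740 ± 83.5 CPM in MDA-MB-436, and the chemokine CXCL5 149 ± 21.7 CPM in BT-549. ANKRD1, a YAP-responsive muscle ankyrin gene, reached 2800 ± 512 CPM in MDA-MB-231, and the collagenase MMP1 3710 ± 3970 CPM, a value with an SD above its mean. The gap junction gene GJA5 reached 530 ± 62.1 CPM in BT-20, the protease MMP7 1120 ± 123 CPM in HCC1143, and the kallikreins KLK6 and KLK10 188 ± 36.5 and 208 ± 55.9 CPM in HCC1937. The keratins KRT13 and KRT81 reached 1690 ± 111 CPM in HCC1806 and 454 ± 45.3 CPM in HCC38. The glutamate transporter SLC1A6 reached 304 ± 25.7 CPM in MDA-MB-468, and the cancer testis gene MAGEA4 939 ± 94.7 CPM in HCC1395 and 919 ± 92.3 CPM in MDA-MB-436. Keratins, CXCL, MAGEA and SERPINB3 genes have near-identical relatives, so their counts depend on how shared reads were assigned.

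Several genes had no or almost no reads in single lines, of which GSTP1 (2 counts in HCC1937), GAS6 (3 counts in MDA-MB-453), HIST1H1D (3 counts in HCC1143) and HIST1H2BH (0.451 CPM in MDA-MB-231) were near 0 in another line too. Against the median of the other lines, the mitochondrial ATPase gene ATAD1 was at least 932-fold lower in HCC1937, the phosphatase subunit PPP2R5E at least 452-fold lower in HCC1187, and the ciliary transport gene IFT74 at least 293-fold lower in HCC38. TCEAL8 was at least 291-fold lower in MDA-MB-453, the AXL ligand GAS6 at least 244-fold lower in HCC70 and the protocadherin PCDH9 at least 37.2-fold lower in MDA-MB-436. The histone genes HIST1H1D and HIST1H2BH were at least 1230-fold lower in MDA-MB-231 and at least 639-fold lower in HCC1143. These bounds use CPM without TMM scaling and a floor of 3 counts over the summed libraries of the line. GSTP1, a glutathione transferase, had 1 count in BT-20 and was 2220-fold lower (95% Poisson interval 399 to 87700). VAMP8 in BT-549 (1840-fold, 330 to 72700), ANP32A in MDA-MB-157 (1860-fold, 334 to 73400) and UBN1 in MDA-MB-468 (1880-fold, 337 to 74200) also had 1 count. TXNIP, an inhibitor of glucose uptake, had 4 counts in HCC1395 (561-fold lower, 219 to 2060), RIC8A 4 counts in HCC1806 (435-fold lower, 170 to 1600) and HIST1H1B 6 counts in Hs578T (911-fold lower, 419 to 2480). Intervals and floors cover counting error only. Neighbouring histone genes near HIST1H1D on chromosome 6 were also near 0 in MDA-MB-231 and in HCC1143. Other genes of this cluster were near 0 in other lines too. HIST1H2BB and HIST1H3C stood at 0.199 and 0.546 CPM in BT-20, 0.348 and 0 CPM in HCC1187, and 1.52 and 0.599 CPM in HCC1395.

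**Figure D1:**
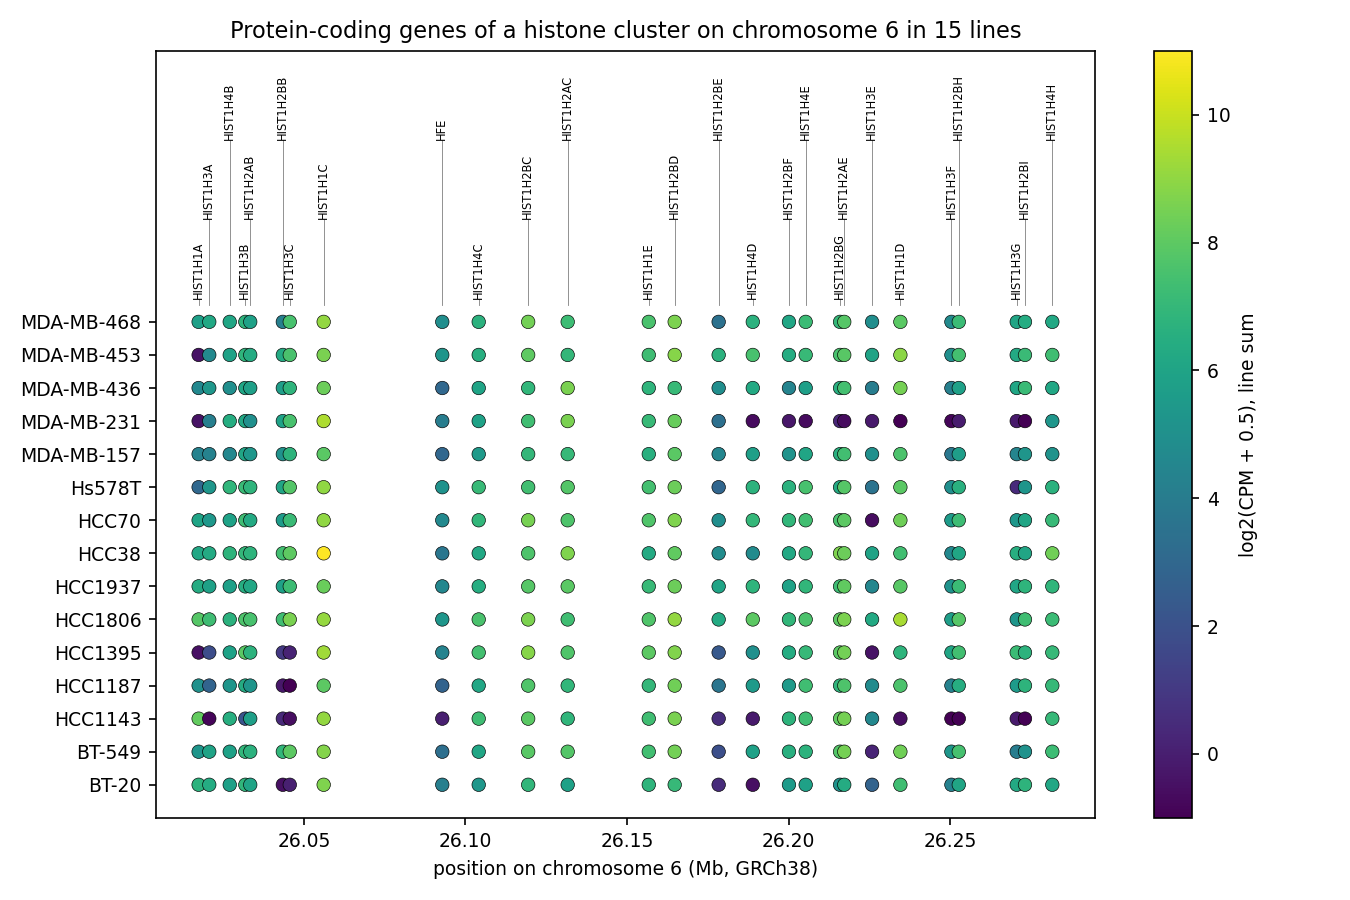
Level of each protein-coding gene in a histone cluster on chromosome 6 (x axis, position in Mb on GRCh38) in each of the 15 lines (y axis). The colour of each point gives log2 of CPM plus 0.5 from the summed libraries of the line, without TMM scaling. HIST1H1D stood at 0 CPM in MDA-MB-231 and 0.189 CPM in HCC1143, against 110 to 688 CPM in the other 13 lines.

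Genes of metabolism also varied between lines. Glutamate dehydrogenase GLUD1, whose relative GLUD2 has nearly the same sequence, stood at 791 ± 61.1 CPM (SD, n = 3) in HCC1806 and 0.576 ± 0.232 CPM in HCC1937, and glutamine synthetase GLUL at 1410 ± 72.3 CPM in HCC70 and 4.01 ± 1.33 CPM in Hs578T. The amino acid transporters SLC1A5 and SLC7A11 were highest in HCC1806, at 239 ± 12.6 and 1260 ± 91.7 CPM. The serine synthesis gene PHGDH ranged from 581 ± 56.4 CPM in MDA-MB-468 to 1.63 ± 0.193 CPM in MDA-MB-231, and PSAT1 from 297 ± 54.8 CPM in HCC1937 to 0.356 ± 0.347 CPM in MDA-MB-453. Lactate dehydrogenase LDHB ranged from 2060 ± 95.9 CPM in HCC1395 to 2.07 ± 0.393 CPM in BT-20, while LDHA stayed between 2140 ± 72.5 CPM (HCC1806) and 311 ± 33.2 CPM (HCC1143). The TCA cycle gene IDH2 ranged from 420 ± 4.99 CPM in HCC70 to 9.75 ± 0.374 CPM in HCC1806. Of 21 glutamine genes, 8 were higher in HCC1806, 11 were lower in MDA-MB-157 and 8 were lower in MDA-MB-453. Of 34 nuclear complex I genes, 33 differed among the lines, with a median fold of 3.32 between the highest and the lowest line. In no line did more than 4 of them pass as higher (MDA-MB-436) or more than 3 as lower.

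Stress and growth programmes differed as well. Of 19 interferon genes, 16 were higher in HCC1937 and in BT-549, the latter with a score of 0.76 ± 1.08 (SD, n = 3) that varied between replicates. Of 19 cholesterol synthesis genes, 14 were higher in HCC70, and of 18 hypoxia genes 14 were higher in Hs578T and in MDA-MB-157. Of 19 NRF2 and glutathione genes, 10 were higher in BT-20 and 12 were lower in MDA-MB-453. Of 13 mRNAs of the mitochondrial genome, 11 were higher in MDA-MB-157, 10 in BT-549, and 12 were lower in HCC1395. The mitochondrial share of a library had r = 0.75 with the number of genes detected over the 45 libraries (not tested), so these differences may in part be technical. Of 44 ribosome biogenesis genes, 24 were lower in MDA-MB-453 and 10 in MDA-MB-157. Of 12 serine and one-carbon genes, 6 were lower in MDA-MB-231. Every measured member of the 33 lists besides complex I differed among the lines, both over all genes and adjusted over the list alone.

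In all, 20224 of 20587 tested genes (98.2%) differed among the 15 lines by edgeR at an adjusted threshold of 0.05, with a common coefficient of variation between replicates of 0.153. Against the mean of the other lines, between 2746 genes (BT-549) and 4297 genes (Hs578T) were higher by at least 1 log2 unit, with a median of 3279. Between 1892 genes (MDA-MB-468) and 4712 genes (HCC70) were lower, with a median of 2317. Among the genes named for single lines, the largest adjusted p was 4.3e-11. Scaling moved the median gene of a line by more than 0.1 log2 units in several lines. With DESeq2 size factors the shift was 0.12 in Hs578T and 0.11 in MDA-MB-157. With scaling from a stricter gene set it was -0.18 in HCC70, 0.17 in MDA-MB-157, 0.16 in Hs578T and 0.12 in HCC1143. The share of higher genes among those that passed moved by at most 9.3 percentage points (MDA-MB-157), under the limit of 10. Without its replicate 2, Hs578T had 2868 higher genes. Without the expression filter, 4488 genes were higher in BT-549 and 9063 in Hs578T.

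MYC (ENSG00000136997.17, chromosome 8, 127735434 to 127741434) was measured in every library, with 73 to 1312 counts. The series concerns breast cancer cells with high MYC, but no label gives a MYC class, so each line was described by its measured level. MYC was highest in MDA-MB-231 (200 ± 48.4 CPM, SD, n = 3), BT-549 (137 ± 12.1 CPM) and HCC1143 (127 ± 33.7 CPM). It was lowest in HCC70 (54.1 ± 4.55 CPM), MDA-MB-157 (34.6 ± 3.51 CPM) and MDA-MB-453 (17.8 ± 4.01 CPM), with an 11.2-fold range between the extremes. The order between these extremes depended on scaling. On the scale of line sums used for slopes and lists, Hs578T (5.71 log2 CPM) lay below HCC70 (6.11). On that scale HCC1395 (7.01) lay above BT-549 (6.97) and HCC1143 (6.81). MDA-MB-231 stayed highest (7.54), and MDA-MB-157 (4.97) and MDA-MB-453 (3.94) stayed lowest. The difference among lines passed by edgeR (adjusted p = 6.75e-19). Against the mean of the other lines, MYC was higher by 1.42 ± 0.12 log2 units (SE) in MDA-MB-231, 0.84 ± 0.12 in BT-549, 0.72 ± 0.12 in HCC1143, 0.42 ± 0.13 in HCC1395, 0.40 ± 0.13 in HCC1187 and in HCC1937, and 0.33 ± 0.13 in MDA-MB-436. It was lower in MDA-MB-453 (-2.31 ± 0.17), MDA-MB-157 (-1.29 ± 0.16), HCC70 (-0.60 ± 0.14) and Hs578T (-0.34 ± 0.14). HCC38, HCC1806, BT-20 and MDA-MB-468 did not pass. Within its own set of sequencing runs, the difference was 0.26 in HCC1143 (adjusted p = 0.13), which no longer passed, -0.35 in HCC38 (adjusted p = 0.049) and 0.37 in HCC1806 (adjusted p = 0.014). Calls were lost for HCC1187 without replicate 1 (0.35) or 3 (0.30), for MDA-MB-436 without replicate 1 (0.32), 2 (0.28) or 3 (0.36) and for Hs578T without replicate 1 (-0.33) or 3 (-0.15). The call for Hs578T was also lost with DESeq2 size factors and with the DESeq2 test (-0.20 each), and with scaling from a stricter gene set (-0.15). HCC38 passed without replicate 1 (0.44) and MDA-MB-468 without replicate 3 (-0.44).

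**Figure D2:**
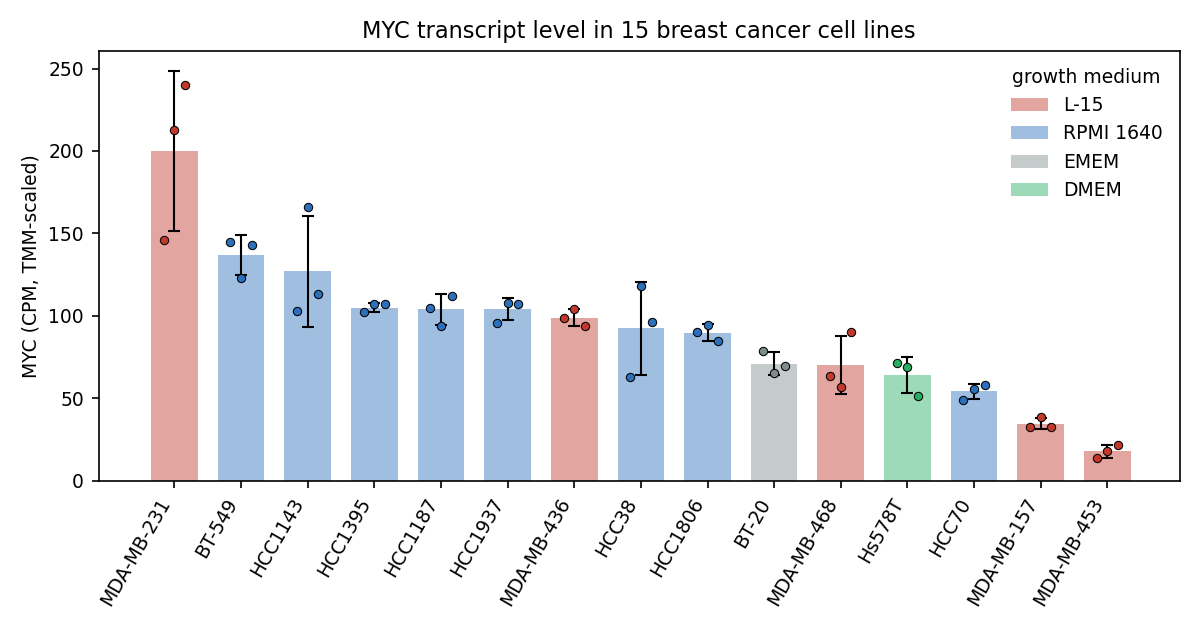
MYC level (y axis, CPM with TMM scaling) in each of the 15 lines (x axis), where bars give the mean, error bars the SD and points the 3 libraries, coloured by growth medium. The 3 libraries of MDA-MB-453 lie below those of every other line, around a mean of 17.8 CPM, and the mean of MDA-MB-231 is 200 CPM.

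The next comparison asked which genes follow MYC across the 15 lines. NFE2L3 (ENSG00000050344.8, chromosome 7, 26152240 to 26187125), a relative of the antioxidant factor NRF2, rose by 2.08 ± 0.35 log2 units (SE) per log2 unit of MYC. Its level was 2.79 ± 0.47 CPM (SD, n = 3) in MDA-MB-453 and 285 ± 52.6 CPM in MDA-MB-231. The fitted increases with the next smallest p-values did not pass. They belonged to the NF-kB pathway genes BIRC3 (2.10 ± 0.44) and RELB (1.53 ± 0.35), the immune receptor CD83, the chromatin protein HMGA1 (1.19 ± 0.29), the chaperone HSPA4 (0.55 ± 0.13), the ribosome assembly genes TSR1 and BYSL, ARHGEF28 and JADE2, with adjusted p from 0.082 to 0.22. Among genes that fell with MYC were the transporter ABCC11 (-2.16 ± 0.28), the growth factor receptor FGFR4 (-2.23 ± 0.29), LRRC31 (-2.09 ± 0.26), the adenylyl cyclase ADCY2 (-1.71 ± 0.23) and the transcription factor TFAP2B (-2.18 ± 0.30). So did the breast differentiation antigen ANKRD30A (-2.13 ± 0.30), the carrier gene SLC16A6 (-1.76 ± 0.25), the cytokine TGFB3 (-1.85 ± 0.27), the secretory pathway factor XBP1 (-1.38 ± 0.21) and CCDC152 (-1.54 ± 0.22), a gene that overlaps another on the opposite strand. In MDA-MB-453, the line with the lowest MYC, FGFR4 reached 811 ± 71.2 CPM, ABCC11 273 ± 21.9 CPM and XBP1 3420 ± 117 CPM. In MDA-MB-231 they stood at 1.48 ± 0.387, 0.82 ± 0.733 and 80.5 ± 2.52 CPM. ERBB2 had a slope of -0.94 ± 0.20 that did not pass (adjusted p = 0.0872), and LDHB 2.08 ± 0.71 (adjusted p = 0.487).

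Of 26614 genes, 1 rose and 40 fell with MYC (edgeR on line sums), and 857 and 953 did so at an unadjusted p under 0.05. DESeq2 called 162 rising and 147 falling genes, and limma-voom with a run block 153 and 268. With growth in L-15 as a covariate edgeR called 0 in either direction, in the 11 lines of runs 3 to 5 it called 2 and 21, and in the 8 RPMI lines 0 and 1. Slopes over the 4 lines of runs 1 and 2 alone were not fitted. Without the expression filter edgeR called 6 rising and 70 falling genes. Without MDA-MB-453, 8 genes fell and 0 rose, and 3 of the 40 genes were among the 8. The median slope of the 40 genes, of which 33 had a value, was then -0.43, against -1.73 over all lines. Without replicate 1 of each line 21 genes fell. In the RPMI lines the slopes of ADCY2 (0.90), TFAP2B (1.29) and ANKRD30A (1.54) had the opposite sign and did not pass.

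Gene groups were set against MYC next, since the series concerns complex I and the TCA cycle in cells with high MYC. Ribosome biogenesis was the only list whose r with MYC passed. Its members EBNA1BP2 (slope 0.78 ± 0.20, SE), LYAR (0.78 ± 0.20), BYSL (0.79 ± 0.20) and TSR1 (0.73 ± 0.18), which act in the assembly of ribosomal subunits, had the smallest p-values. Of the 44 measured members, 14 rose when adjusted over the list alone, 0 over all genes, and the median slope was 0.46. The score correlated with MYC with r = 0.85 over 15 lines (permutation p = 0.0002, adjusted p = 0.0068 over 34 lists) and rho = 0.70 (permutation p = 0.00452, adjusted p = 0.102). In the 11 lines of runs 3 to 5 r was 0.97, and in the 8 RPMI lines 0.54 (permutation p = 0.162). Without MDA-MB-453 and MDA-MB-157, the lines farthest from the median MYC, r was 0.48 (permutation p = 0.0958), so the relation was weaker and not detected without them. With only MDA-MB-157 or only MDA-MB-453 left out r was 0.81 or 0.72, and the call was lost each time. The camera test with an estimated correlation also passed (adjusted p = 0.0164).

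For respiratory chain genes no list passed against MYC. Nuclear complex I genes had r = 0.15 (permutation p = 0.599, adjusted p = 0.754) and rho = 0.15, and 0 of 34 passed over all genes or adjusted over the list alone. Among them NDUFA12 (0.38 ± 0.16) and NDUFS4 (0.36 ± 0.17) reached an unadjusted p of 0.0331 and 0.045. Complex I assembly factors had r = 0.43, mRNAs of the mitochondrial genome -0.19, complex III 0.06, complex IV 0.33 and complex V 0.03. TCA cycle enzymes had r = 0.09 (adjusted p = 0.825) and rho = 0.00. Without MDA-MB-453 and MDA-MB-157 the sign was the opposite for mRNAs of the mitochondrial genome (0.15) and for TCA cycle enzymes (-0.08). In runs 3 to 5 r was 0.20 for complex I and 0.28 for the TCA cycle, and in the RPMI lines -0.46 (permutation p = 0.267) and -0.57 (permutation p = 0.141). With scaling from a stricter gene set, the form computed first, the sign changed for both, to -0.23 for complex I and -0.19 for the TCA cycle, as it did for complex III (-0.27), complex V (-0.30) and pyruvate entry (-0.17). Glutamine uptake and use had r = 0.63 (permutation p = 0.014, adjusted p = 0.0973) and rho = 0.33, and r = -0.03 without MDA-MB-453 and MDA-MB-157. In runs 3 to 5 r was 0.75. Its members PFAS (0.89 ± 0.29), PPAT (0.52 ± 0.20) and CTPS1 (0.50 ± 0.20), which use glutamine nitrogen for nucleotides, did not pass (smallest adjusted p = 0.463). GLUD1 had a slope of 0.05 ± 0.36, and of -0.01 with the stricter gene set.

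The other lists did not pass either. Cytosolic ribosomal proteins had r = 0.65, other textbook MYC targets 0.63 and the mitochondrial ribosome 0.61, each with an adjusted p of 0.0973. Integrated stress response had r = 0.56, mitochondrial biogenesis regulators 0.55, cell cycle 0.46, interferon 0.38, basal keratinocyte genes 0.37 and serine and one-carbon metabolism 0.36. By rank, biogenesis regulators (rho = 0.69) and cytosolic ribosomal proteins (0.65) were near ribosome biogenesis (0.70), and no list passed by rho. Without MDA-MB-453 and MDA-MB-157, r was 0.61 for biogenesis regulators (permutation p = 0.0259) and 0.55 for cytosolic ribosomal proteins (permutation p = 0.0523). Fatty acid oxidation and NRF2 and glutathione genes each had r = 0.32, glycolysis 0.30, the MYC network 0.26, the 8q24 neighbours of MYC and histones 0.17, and cholesterol synthesis and mesenchymal genes 0.16. Pyruvate entry had r = 0.04, epithelial genes -0.10, endothelial genes -0.12, hypoxia genes -0.13, fibroblast genes -0.36, blood cell genes -0.38, luminal genes -0.51 and short and nuclear RNAs -0.57. Without MDA-MB-453 and MDA-MB-157 the sign was the opposite for integrated stress response (-0.41), NRF2 and glutathione (-0.33), serine and one-carbon (-0.28), fatty acid oxidation (-0.20), histone (-0.15), cholesterol and basal keratinocyte (-0.13 each), cell cycle (-0.08), 8q24 (-0.04), mesenchymal (-0.01) and endothelial genes (0.11). In runs 3 to 5 r was 0.83 for integrated stress response, 0.75 for cell cycle, 0.70 for serine and one-carbon genes, 0.53 for biogenesis regulators and 0.50 for fatty acid oxidation. It was 0.77 for other textbook MYC targets, 0.75 for cytosolic ribosomal proteins, 0.67 for the mitochondrial ribosome and -0.72 for short and nuclear RNAs. In the RPMI lines these 4 were 0.24, 0.15, -0.14 and -0.87 (unadjusted permutation p = 0.00818 for the last). Epithelial genes had -0.73 there (unadjusted permutation p = 0.0365). Of 18 luminal genes, TFAP2B and XBP1 fell over all genes and 6 fell when adjusted over the list alone. Of 9 fibroblast genes, 0 fell over all genes and 4 when adjusted over the list alone, among them COL3A1 (-3.14 ± 0.98) and PDGFRB (-1.85 ± 0.62). In the other 31 lists 0 members passed either way.

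**Figure D3:**
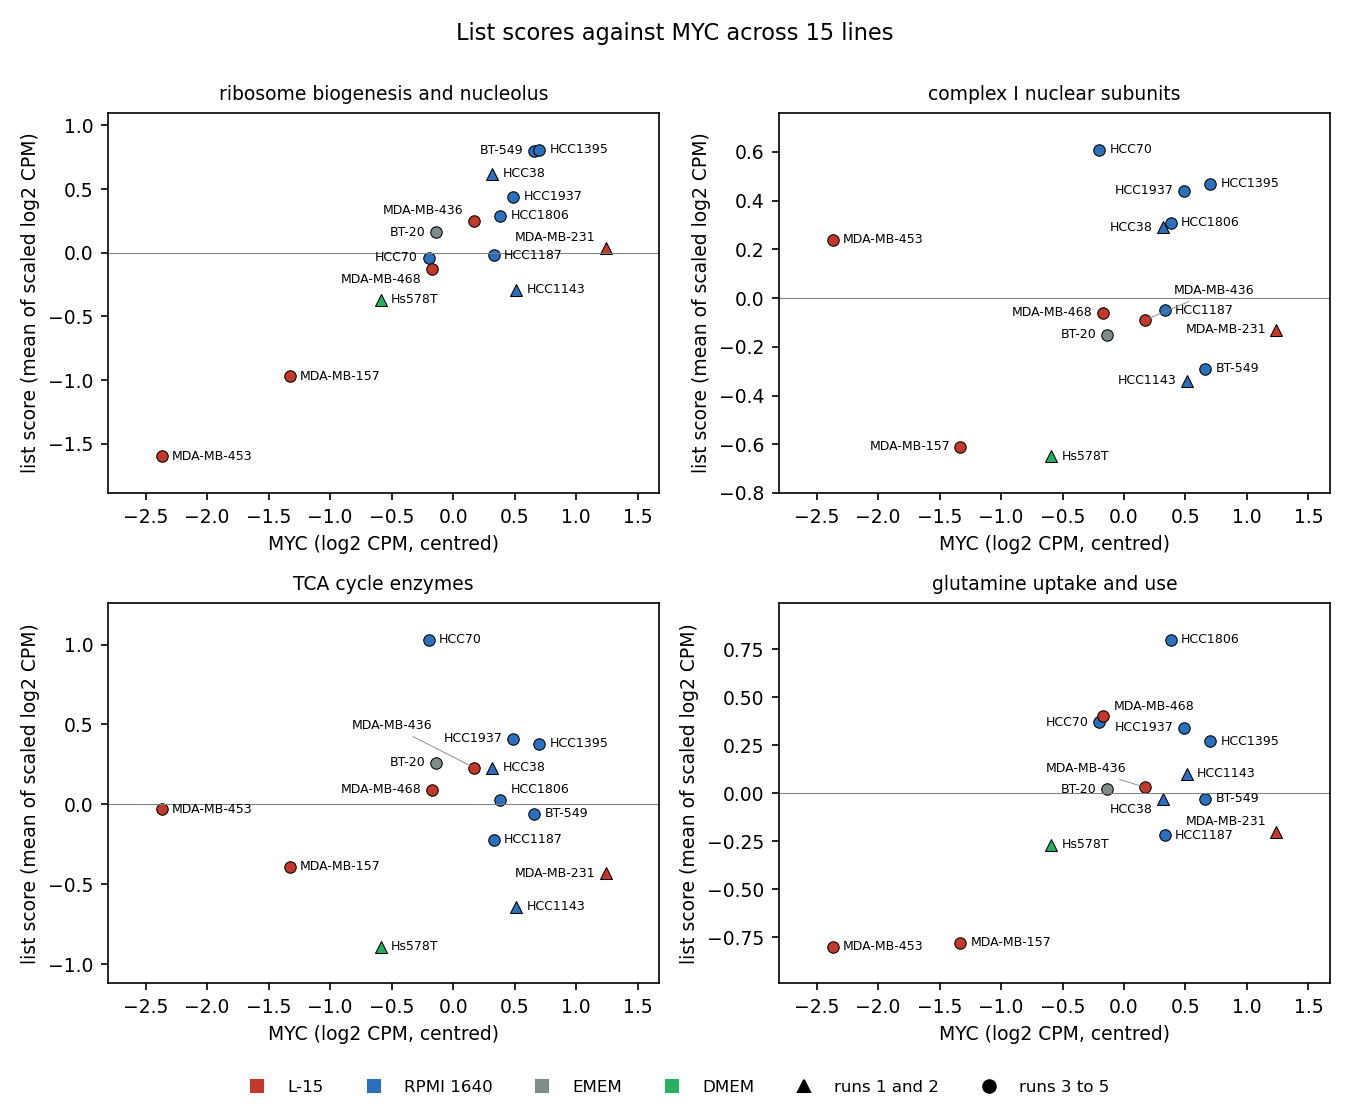
Scores of 4 gene lists (y axis, mean of scaled log2 CPM) against MYC (x axis, centred log2 CPM) for the 15 lines, coloured by growth medium, with triangles for runs 1 and 2 and circles for runs 3 to 5. The ribosome biogenesis score falls to -1.60 in MDA-MB-453 and -0.97 in MDA-MB-157, while the complex I score of MDA-MB-453 is 0.24.

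The series title links complex I to the TCA cycle fed by glutamine, and the complex I score was therefore set against 10 lists. TCA cycle enzymes were highest in HCC70 (score 1.03) and lowest in Hs578T (-0.89), which with this scaling of line sums were also the extremes of complex I (0.61 and -0.65). With the stricter gene set for scaling, the extremes of complex I were MDA-MB-453 (0.62) and BT-20 (-0.36), and from single libraries MDA-MB-453 was highest (0.55). The scores of Hs578T varied widely between its libraries. From single libraries they were -0.84 ± 0.82 (SD, n = 3) for the TCA cycle and -0.50 ± 0.75 for complex I. The correlation was r = 0.83 (permutation p = 0.00026, adjusted p = 0.0013) with rho = 0.79 (permutation p = 0.00092), r = 0.70 without HCC70 and Hs578T, and r = 0.75 in runs 3 to 5. Complex IV had r = 0.88, complex V 0.80, the mitochondrial ribosome 0.74 and complex I assembly factors 0.65, with adjusted p from 0.0003 to 0.0149. The mRNAs of the mitochondrial genome had r = -0.66 (adjusted p = 0.0149). By rank, rho was 0.86 for complex IV, 0.73 for complex V, 0.72 for the mitochondrial ribosome and -0.67 for the mitochondrial genome, while assembly factors did not pass (rho = 0.56, adjusted p = 0.0556). Glutamine uptake and use (0.51, adjusted p = 0.0636), complex III (0.51), pyruvate entry (0.35) and glycolysis (-0.01) did not pass. Without HCC70 and Hs578T, r was 0.80 for complex IV, 0.71 for complex V, 0.67 for the mitochondrial ribosome and -0.75 for the mitochondrial genome. In runs 3 to 5 these were 0.84, 0.72, 0.73 and -0.75.

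These correlations changed with the genes used for scaling. With the stricter gene set, r for the TCA cycle was 0.39 (adjusted p = 0.459), that for glutamine use was -0.22 and that for pyruvate entry -0.11, and 0 of the 10 lists passed. It was 0.55 for complex IV, 0.29 for complex V, 0.24 for the mitochondrial ribosome, 0.38 for assembly factors and -0.28 for the mitochondrial genome. The change of scale between both sets ran from -0.32 log2 units (HCC70) to 0.29 (Hs578T) and had r = -0.82 with the complex I score (permutation p = 0.00031). With the shift held constant, r for complex I and the TCA cycle was 0.45 (permutation p = 0.0944). The larger gene set was made the main one after results with the stricter set had been seen.

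**Figure D4:**
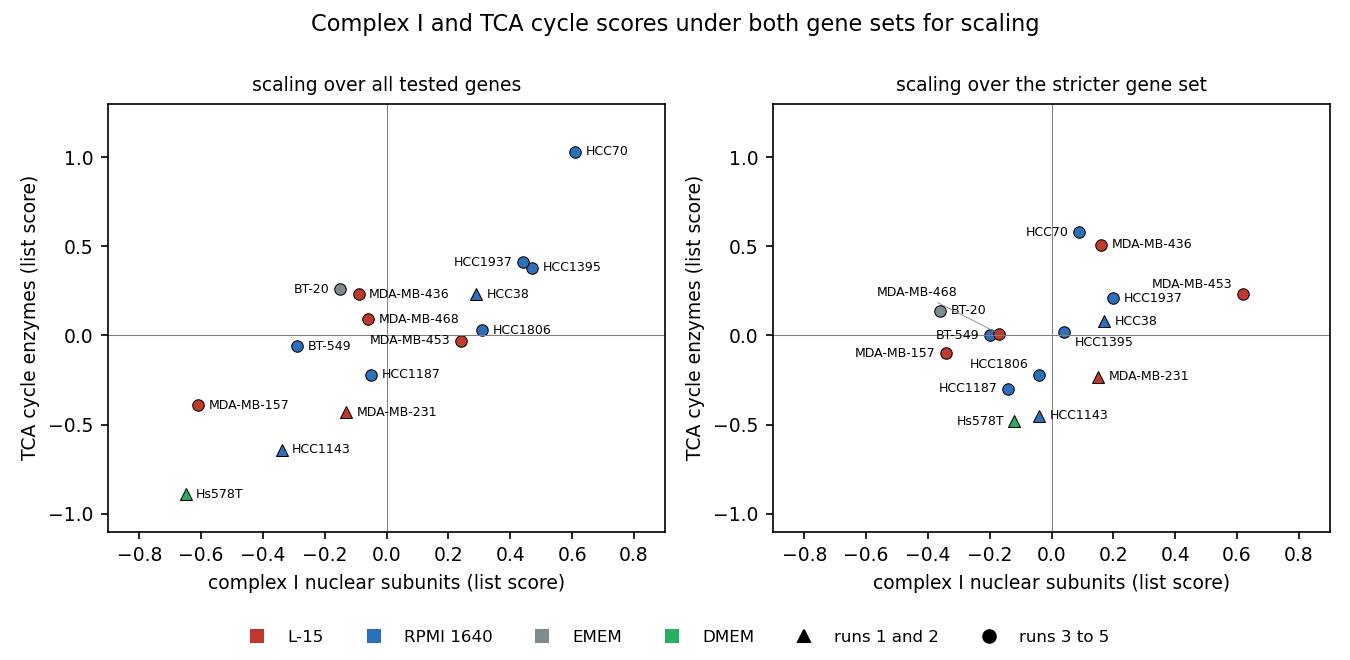
Scores of TCA cycle enzymes (y axis) against those of nuclear complex I genes (x axis) for the 15 lines, both as means of scaled log2 CPM, with scaling over all tested genes in the left panel and over the stricter gene set in the right panel. The correlation is 0.83 on the left and 0.39 on the right.

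Lines grown in L-15 were compared with lines grown in RPMI 1640, because media can alter metabolic genes. No gene passed. SMC2 (ENSG00000136824.18, chromosome 9, 104094260 to 104141417), a condensin subunit, averaged 126 ± 32.6 CPM (SD, n = 5) in L-15 and 418 ± 119 CPM (n = 8) in RPMI, and the replication factor MCM10 48.3 ± 14.6 and 169 ± 56.3 CPM. TPX2, a spindle factor, averaged 222 ± 47.2 and 550 ± 130 CPM, the helicase subunit MCM2 72.3 ± 32.7 and 230 ± 68.5 CPM, and SMC4 292 ± 97.1 and 750 ± 250 CPM. POP1, TGS1, OTUD6B, CYP27C1 and NUP62 also averaged less in L-15. CXorf38 averaged 110 ± 63 CPM in L-15 and 17.6 ± 6.95 CPM in RPMI, the deacetylase HDAC6 97.2 ± 58 and 28 ± 9.73 CPM, and the cytokine IL11 38.1 ± 56.4 and 0.938 ± 0.803 CPM. In L-15, PDGFRB averaged 29.6 ± 60.9 CPM, ADAMTS2 56.3 ± 121, COL5A3 18.3 ± 37.9, CPED1 25 ± 31.1, OSBPL5 42.5 ± 46.1, CDYL2 20.3 ± 20.8 and ATP6V0A4 15.9 ± 22.1 CPM, more than in RPMI. In these genes and IL11, 8 of the 10 named as higher, the SD in L-15 was above the mean. Glycolytic genes PKM (-1.05 ± 0.37 log2 units, SE) and GAPDH (-0.94 ± 0.33) and the kinase PDK4 (2.81 ± 0.87) did not pass over all genes, with adjusted p from 0.305 to 0.345. By edgeR on line sums, 0 of 20505 genes were higher and 0 lower (smallest adjusted p = 0.191), and 1011 and 738 were so at an unadjusted p under 0.05. DESeq2 called 178 higher and 255 lower, and limma-voom with a run block 58 and 180. All 5 L-15 lines belong to the MDA-MB collection and no RPMI line does, so medium and line origin cannot be told apart.

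Cell cycle genes differed between media as a list. Their score averaged -0.69 ± 0.39 (SD, n = 5) in L-15 and 0.43 ± 0.27 (n = 8) in RPMI, a difference of -1.11 (exact permutation p = 0.000777, the smallest that 1287 splits can give, adjusted p = 0.0264 over 34 lists). Each of the 5 L-15 lines lay below each of the 8 RPMI lines. Among the 30 members, MCM2 (-1.67 ± 0.35 log2 units, SE), MCM5 (-1.63 ± 0.38), MCM4 (-1.35 ± 0.31) and the licensing factor CDC6 (-1.30 ± 0.37) were lower when adjusted over the list alone, as were 10 members in all, against 0 over all genes. In the lines of runs 3 to 5 the difference was -1.08 with an adjusted p of 0.162, the smallest that a single list could reach with 4 against 6 lines. In runs 1 and 2 MDA-MB-231 scored -1.0, below HCC1143 (0.17) and HCC38 (0.50), and no test was made. Without MDA-MB-453 (-1.12), MDA-MB-231 (-1.09), MDA-MB-157 (-1.09) or MDA-MB-436 (-1.18) the adjusted p was 0.0687, the smallest that a single list could reach with 4 against 8 lines, so these lost calls do not bear on stability. Without MDA-MB-468 the difference was -1.23 and the call was kept. With 4 against 8 lines this needs other lists with a small p too, so it does not bear on stability either.

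**Figure D5:**
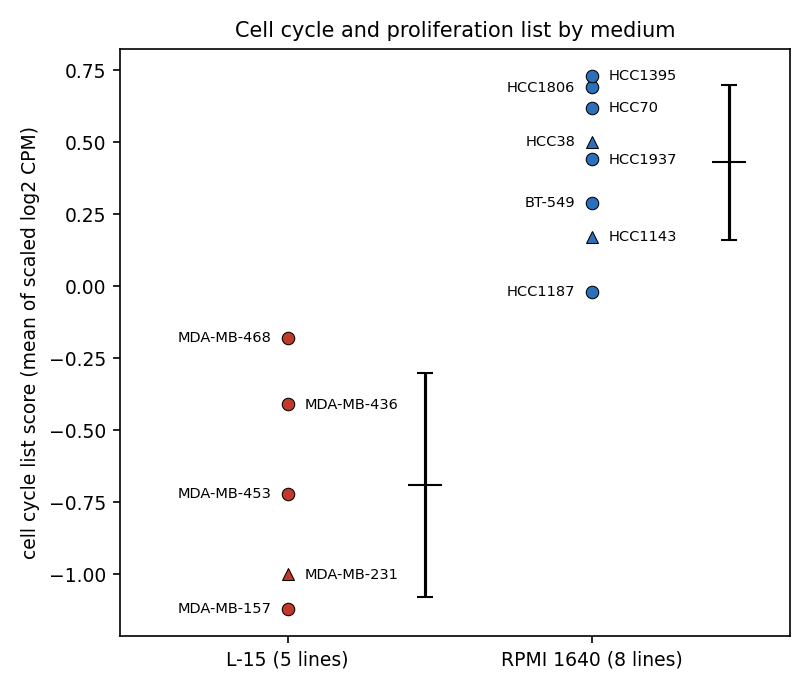
Cell cycle list score (y axis, mean of scaled log2 CPM) of the 5 L-15 lines and the 8 RPMI 1640 lines, with triangles for runs 1 and 2, circles for runs 3 to 5, and the mean and SD of each group beside the points. The highest L-15 line, MDA-MB-468, is at -0.18 and the lowest RPMI line, HCC1187, at -0.02.

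No other list passed by medium. Histones differed by -0.86 (exact p = 0.0155, adjusted p = 0.164), endothelial genes by 0.88, 8q24 neighbours and serine and one-carbon genes by -0.70 each, interferon genes by -0.75, ribosome biogenesis by -0.69 and basal keratinocyte genes by -0.68. Fibroblast genes differed by 0.62, mitochondrial genome mRNAs by 0.56, blood cell genes and cholesterol synthesis by 0.52 and -0.52, integrated stress response and other MYC targets by -0.51 each, and hypoxia genes by 0.48. The mitochondrial ribosome differed by -0.46, epithelial genes by -0.44, glutamine use by -0.37, pyruvate entry and short RNAs by 0.32 each, fatty acid oxidation by -0.32, complex IV by -0.28 and cytosolic ribosomal proteins by -0.27. Assembly factors differed by -0.24, complex V by -0.23, the MYC network by -0.21, glycolysis by -0.13, biogenesis regulators by -0.12, luminal genes by 0.10, complex III by -0.06, NRF2 genes by -0.05 and mesenchymal genes by 0.05. Complex I differed by -0.15 and the TCA cycle by -0.12, and each was 0.13 with scaling from the stricter gene set, which moved the median gene by 0.16 log2 units. Adjusted over the list alone, 7 of 21 basal keratinocyte genes were lower, among them DSG3 (-7.36 ± 1.80 log2 units, SE), and 5 of 9 fibroblast genes were higher, among them PDGFRB (6.06 ± 1.20). Of 15 luminal genes, 3 were higher and 1 lower, the steepest being TFAP2B (5.73 ± 1.37) and DHRS2 (-3.50 ± 1.19). In ribosome biogenesis NOP56 (-1.71 ± 0.44) and NIP7 (-1.27 ± 0.34) were lower. Assembly factor ACAD9 (-1.14 ± 0.32), MTHFD1 (-1.13 ± 0.32), CDK4 (-1.15 ± 0.30) and OAS3 (-2.48 ± 0.56) were lower and NEAT1 (1.37 ± 0.35) was higher, 1 in each list. None of these passed over all genes. MYC averaged 5.81 ± 1.39 log2 CPM in L-15 and 6.71 ± 0.28 in RPMI (exact permutation p = 0.0963).

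A technical comparison asked how far the sequencing runs differ. Ribosomal protein and histone genes were among those that did. Of 73 cytosolic ribosomal protein genes, 23 differed between runs 3, 4 and 5 within the 11 lines that were in all 3 runs, and of 12 histone genes 8 did. Of 34 nuclear complex I genes 5 differed, of 18 TCA cycle genes 1, of 21 glutamine genes 3, of 44 ribosome biogenesis genes 5 and of 30 cell cycle genes 2. Over all genes, 1097 of 19350 (5.67%) differed by edgeR, 175 of them by more than 1 log2 unit. They comprised 841 protein-coding genes, 112 antisense genes, 30 processed pseudogenes, 23 snoRNAs and 17 snRNAs among other types. Each line of this set had 1 library in each run, so run differences add to the spread between replicates and do not separate these lines. In these lines the replicate number and the run coincide. Differences tied to the replicate number thus cannot be told apart from those of sequencing.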

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

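The tests of chance splits by medium were chosen after the result was seen, while the other tests in this part were chosen before it. Single lines were compared with the other lines of their medium in 110 groups of 5 or 8 lines. Chance alone would set a line apart in about 5 percent of them, and 5 groups had such a line, about as many as by chance. The groups covered the list scores, MYC and the genes named by medium. Those genes, among them COL5A3 and CXorf38, were picked for a small p in these data, so the chance rate need not hold for them. Among the 5 L-15 lines, the score of short and nuclear RNAs was 1.17 in MDA-MB-453 and 0.07 in the nearest line, a gap of 0.758 of the whole range. COL5A3, a collagen gene, stood at 6.43 log2 CPM in MDA-MB-157 and 0.81 in the nearest L-15 line (0.844 of the range). Among the 8 RPMI lines, the 8q24 neighbours of MYC scored -1.02 in HCC1187 and 0.18 in the nearest line (0.687 of the range). MYC stood at -0.20 on the centred log2 scale in HCC70 and 0.32 in the nearest RPMI line (0.583 of the range). CXorf38 stood at 1.90 log2 CPM in HCC1143 and 3.92 in the nearest RPMI line (0.708 of the range).

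The genes that fell with MYC were weighed first. Without MDA-MB-453, the line with the lowest MYC, 9 of the 40 genes had an unadjusted p under 0.05 (33 had a value), against 37 to 40 without each of the other lines, so this line may carry most of the slopes, and 37 of the 40 genes were highest in it. With L-15 as a covariate the median slope by edgeR was -1.69 (median SE 0.41) against -1.73 (median SE 0.26). No call was left, as the F statistics fell, which the larger SE restates. The smallest adjusted p by edgeR was then 0.563, and the largest unadjusted p of the 40 genes was 0.00696. Allowing for a shift shared by the L-15 lines thus left the median slope almost unchanged. This cannot decide on growth medium, since MDA-MB-453 is itself an L-15 line. A shared term cannot take up slopes carried by 1 such line, and without MDA-MB-453 the median slope was -0.43. Chance cannot be excluded either, since 13 of 100 orders of the MYC values gave as many falling genes (real 40, highest other 89) and 37 of 100 gave as many rising genes (real 1, highest other 12). NFE2L3, the rising gene, had an adjusted p of 0.22 without MDA-MB-453. Other properties of MDA-MB-453, such as its luminal genes, stay open and were not tested.

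Chance splits were also counted for the other fits. For genes that differ among lines, 1 of 21 splits, the real one, gave as many (real 20224, highest other 700). The same held for higher genes (1 of 21, lowest line 2746, highest other 682) and for lower genes (1 of 21, lowest line 1892, highest other 141), where only some groups of each split were contrasted. Each library was closest to its own line, and random groups mix lines. These splits therefore say only that libraries of a line are alike, as technical replicates would be too. For runs 3 to 5, where libraries were reassigned within lines, 1 of 30 gave as many (real 1097, highest other 1), and chance can be excluded there. Run and replicate number coincide in these lines, so the splits cannot tell which of them matters. For medium the real counts were 0 higher genes by edgeR (1011 at an unadjusted p under 0.05, 178 by DESeq2) and 0 lower genes (738 unadjusted, 255 by DESeq2). Any split gives at least 0, so 100 of 100 splits did so by construction for higher and for lower genes, which says nothing about chance. Apart from that, the highest of the other splits called 195 higher and 274 lower genes, which can point to a structure of the lines or to genes that vary together, and neither was tested.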

How the results depend on the processing

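The intercept-only filter was the form computed first, and the main filter replaced it after its results had been seen. Scaling from the genes it keeps (the stricter scaling) and the removal of Hs578T replicate 2 were chosen after seeing the data. Except where a reason is given, the cause was not tested.

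Of 441 values of 36 gene counts, 378 lay within 1.5 times the count in the report and 63 moved. Of 149 values of MYC in single lines, 130 kept direction and call, 13 lost the call, 3 gained it, 2 moved and 1 reversed. The 60 genes named for single lines kept direction and call in all 596 values. For lists against MYC 819 of 917 values did so, for lists against complex I 221 of 250, for lists by medium 646 of 680, for genes named by the MYC slope 1032 of 1198 and for genes named by medium 405 of 434.

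Without the fold minimum more genes count by construction. The higher and lower genes were then 6024 and 4345 in BT-20, 5890 and 4362 in BT-549, 6332 and 5029 in HCC1143, 6196 and 4701 in HCC1187, 6440 and 5678 in HCC1395, 6473 and 4868 in HCC1806, 6375 and 4213 in HCC1937, and 6070 and 4362 in HCC38. They were 6481 and 4980 in Hs578T, 6450 and 5390 in MDA-MB-157, 5552 and 4836 in MDA-MB-231, 6307 and 5004 in MDA-MB-436, 6330 and 5356 in MDA-MB-453, and 6013 and 4168 in MDA-MB-468, and 7012 were higher in HCC70. Without the filter the higher genes were 4488 in BT-549, 5795 in HCC1143, 9063 in Hs578T, 6915 in MDA-MB-157, 5256 in MDA-MB-231, 6423 in MDA-MB-436 and 7122 in MDA-MB-453. With the replicate block the genes differing among the 15 cell lines numbered 20313, against 20224 without it. Without replicate 1, 2 or 3 of every line it was 19452 to 20168, and without Hs578T replicate 2 20753.

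Without each replicate of the line in turn, higher genes were 2806 to 2942 in BT-20, 2562 to 2807 in BT-549, 3609 to 3700 in HCC1143, 3076 to 3268 in HCC1187, 2981 to 3114 in HCC1395, 3231 to 3446 in HCC1806, 2844 to 3152 in HCC1937, 2789 to 2850 in HCC38, 3725 to 4026 in HCC70, 2868 to 5689 in Hs578T, 3965 to 4056 in MDA-MB-157, 2691 to 3091 in MDA-MB-231, 3027 to 3393 in MDA-MB-436, 3467 to 3542 in MDA-MB-453 and 2843 to 3058 in MDA-MB-468. Lower genes were 2100 to 2385, 2052 to 2331, 2146 to 2236, 2492 to 2583, 2716 to 3927, 2436 to 2481, 1888 to 2059, 1770 to 1991, 3692 to 4353, 1695 to 2137, 2515 to 2597, 2047 to 2157, 2167 to 2211, 2937 to 3037 and 1730 to 1799 in the same order.

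MYC within the own run set was 0.00 in BT-20, 0.26 in HCC1143, 0.37 in HCC1806 and -0.35 in HCC38, where it reversed. Without the filter it was 0.34 in HCC1187 and 0.30 in MDA-MB-436, which lost their calls. Hs578T lost its call with DESeq2 size factors and with the DESeq2 test (-0.20 each) and with the stricter scaling (-0.15). Without single replicates MYC was -0.29 to -0.13 in BT-20, 0.77 to 0.86 in BT-549, 0.48 to 0.84 in HCC1143, 0.43 to 0.47 in HCC1395, 0.16 to 0.24 in HCC1806, 0.38 to 0.46 in HCC1937, -0.59 to -0.52 in HCC70, -1.38 to -1.28 in MDA-MB-157, 1.23 to 1.60 in MDA-MB-231 and -2.51 to -2.21 in MDA-MB-453. It was 0.30 to 0.42 in HCC1187, with the call lost without replicate 1 (0.35) or 3, and 0.28 to 0.36 in MDA-MB-436, lost without replicate 1 (0.32), 2 or 3. It was -0.39 to -0.15 in Hs578T, lost without replicate 1 (-0.33) or 3, -0.01 without replicate 2 to 0.44 without replicate 1 in HCC38, which gained a call there, and -0.44 without replicate 3, a call, to -0.07 in MDA-MB-468.

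Genes rising and falling with MYC were 6 and 70 without the filter, 162 and 147 by DESeq2, 153 and 268 by limma-voom with the replicate block, 2 and 21 in runs 3 to 5 and 0 and 1 in RPMI lines, where fewer lines were tested. With L-15 as a covariate edgeR called 0 and 0, as the F statistics fell. With MYC from other replicates 3 rose, and with the intercept-only filter 2. Leave-one-out gave 0 (without MDA-MB-157 or MDA-MB-453) to 2 rising genes (without BT-549, HCC1187, HCC1395, HCC1806 or MDA-MB-231) and 8 (without MDA-MB-453) to 48 falling genes. Without replicates it was 1 rising and 21 (without replicate 1) to 44 falling. In RPMI lines the slopes of ADCY2 (0.90), TFAP2B (1.29) and ANKRD30A (1.54) reversed, and that of ANKRD30A was -2.50 (without MDA-MB-231) to 0.45 (without MDA-MB-453) with 1 line left out.

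In RPMI lines, with filter, scaling and scores recomputed over these 8 (the report takes them from 15-line scores, 0.54 for ribosome biogenesis), r with MYC was -0.44 for complex I, -0.02 for assembly factors, 0.18 for mitochondrial mRNAs, -0.55 for the TCA cycle, -0.11 for glutamine use, -0.07 for glycolysis and 0.62 for ribosome biogenesis, which lost its call. With MYC from other replicates it was -0.12 for complex I and -0.09 for the TCA cycle, and with the intercept-only filter -0.23 and -0.19. With that filter r with complex I was 0.39 for the TCA cycle, a lost call, and -0.22 for glutamine use. Leave-one-out r with MYC was -0.03 (without MDA-MB-157, 0.00 without Hs578T) to 0.42 for complex I, 0.27 to 0.47 for assembly factors, -0.33 to -0.02 for mitochondrial mRNAs, -0.08 (without Hs578T, -0.02 without MDA-MB-157) to 0.17 for the TCA cycle, 0.42 to 0.73 (a call, without MDA-MB-231) for glutamine use, 0.05 to 0.40 for glycolysis and 0.72 to 0.92 for ribosome biogenesis, whose call was lost without MDA-MB-157 (0.81) or MDA-MB-453. Without replicates these were -0.07 (replicate 2) to 0.18, 0.29 to 0.39, -0.31 to -0.12, -0.05 (replicate 2, -0.03 without replicate 3) to 0.09, 0.58 to 0.62, 0.22 to 0.30 and 0.84 to 0.86, and -0.02 for the TCA cycle without Hs578T replicate 2. With complex I, the TCA cycle had 0.73 to 0.85 without lines and 0.70 to 0.82 without replicates, and glutamine use 0.38 to 0.72 (a call, without MDA-MB-453) and 0.28 to 0.54.

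By medium, DESeq2 called 178 higher and 255 lower genes and limma-voom with the replicate block 58 and 180, against 0 and 0 by edgeR (1011 and 738 unadjusted), also without each line or replicate. The cell cycle difference was -1.08 in runs 3 to 5, a lost call, -1.1 to -1.05 without replicates and -1.23 to -1.07 without lines, with the call lost without MDA-MB-157 (-1.09), MDA-MB-231 (-1.09), MDA-MB-436 (-1.18) or MDA-MB-453 (-1.12). With 4 L-15 lines no list could pass alone in these settings, so the lost calls say nothing on stability. With the stricter scaling complex I and the TCA cycle differed by 0.13 each. Without lines they were -0.29 to -0.06 and -0.23 to 0.00 (without HCC70), glutamine use -0.57 to -0.26 and glycolysis -0.29 to -0.02. Without replicates they were -0.08 to -0.06, -0.07 to -0.01, -0.33 and -0.11 to -0.07. Depth limits single genes near the floor: libraries held 2312138 to 14653677 counts, and MYC had 73 to 1312 counts in each.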

Other observations

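All tests in this part (neighbouring genes, shared reads, run set and short RNA) were chosen after the results had been seen. Some genes expressed in most lines were silent in 1 line or a few, and several lay side by side. On chromosome 9 of MDA-MB-231 the genes KLHL9, MTAP, CDKN2A, CDKN2B and ELAVL2 had 1 count in all over 2496667 bases, and in HCC38 CDKN2A, CDKN2B and ELAVL2 had 0 counts. CDKN2A also had 1 count in BT-20. CDKN2A and CDKN2B encode inhibitors of cell cycle kinases, and MTAP an enzyme of methionine salvage. HCC38 also lacked PLAA, IFT74 and C9orf72 (3 counts in all). SHLD2, MINPP1, PAPSS2 and ATAD1 on chromosome 10 had 2 counts in HCC1937, PPP2R5E and WDR89 on chromosome 14 had 1 count in HCC1187, and ANKS3 and ROGDI on chromosome 16 had 1 count in MDA-MB-468. The collagen genes COL6A1 and COL6A2 had 3 counts in MDA-MB-468, TCEAL8 and TCEAL9 3 counts in MDA-MB-453, and ZMYM5 and ZMYM2 6 counts in MDA-MB-157. The remaining segments were histone genes of chromosome 6 in HCC1143 and MDA-MB-231, as in the plot of the histone cluster.

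These silent genes were weighed as a pattern. Of 8672 genes with a median of at least 10 CPM over the other lines, 114 had 0 to 3 counts in a line, in 136 gene and line pairs. A hypothesis is that a whole segment was lost or silenced: 20 neighbouring pairs were found, against at most 3 in 10000 random placements (mean 0.154), which is consistent with it. Reads shared between near-identical copies are argued against as the whole source, since 16 neighbouring pairs lay outside the histone clusters and the MHC, against at most 3 at random, while inside these clusters shared reads stay open. DNA was not analysed here, so loss and silencing cannot be separated.

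Lines of the 2 sets of runs also differed in short RNAs. In the 4 lines of runs 1 and 2, 116 genes lay below all 11 lines of runs 3 to 5, and 54 lay above them. A hypothesis is that the run set lowered these genes: 4 of all choices of 4 lines gave as many lower genes, the real one included (highest other 297), which may point to the run set, while 46 choices gave as many higher genes. Short RNA genes made up 19% of the 116 (22 genes), against 1.79% of 31033 eligible genes, and 8 of 1073 other choices of 4 lines with at least 5 such genes had a share as large (highest 40%), so recovery of short RNA could differ between the sets of runs. The lines of the 2 sets are different lines, so a property shared by these 4 lines stays open as a biological explanation and was not tested.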
